A study of Mus musculus with 24 samples.

How the data were processed

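Transcript levels were measured on Illumina mouse bead arrays in 24 samples, with 4 arrays per genotype in heart, bone and white adipose tissue. Total RNA was extracted with Trizol and RNeasy columns, checked on gels, and amplified to biotin-labelled cRNA with a MessageAmp kit, per the labels' protocols. Images were read in GenomeStudio 2011.1, per the submitters' processing notes. Sample sex, age and strain came from the labels.

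The authors deposited a table of background-subtracted, normalized intensities with a detection p-value for each probe and array. In that table the arrays of a tissue share an upper quartile, between 111 and 112 in heart, 224 and 225 in bone, and 305 and 307 in white adipose tissue, and the lowest values lie below 0. A second set of deposited values holds raw intensities with no background subtraction or normalization. The content of these sets was read from the values themselves and is the reverse of what had been assumed when the plan was written, so the raw intensities were taken from the second set and the authors' normalized intensities served as an alternative. Within every array the rank correlation between both sets rounds to 1. How the authors' software scaled the intensities is not given in the sources used here.

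Raw intensities were background-corrected with the normexp model, using detection p-values in place of control probes, raised by an offset of 16, quantile-normalized within each tissue and put on a log2 scale, in limma 3.58.1 under R 4.3.3. A probe was kept in a tissue when its deposited detection p-value was under 0.05 in at least 4 of the 8 arrays. The kept probes numbered 11015 in heart, 12917 in bone and 12648 in white adipose tissue. Of 25697 probes, 23978 carry 1 gene symbol, 0 carry several and 1719 carry none. The named probes stand for 16593 genes, and 23962 of them matched the reference table by Entrez number, which changed 0 symbols. Where several probes of a gene were kept, the probe with the highest mean level stood for the gene, which left 8535, 9460 and 9292 genes in heart, bone and white adipose tissue.

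Heterozygous and wild-type arrays were compared within each tissue by linear models with limma's moderated test, with a trend of variance on mean level. P-values were adjusted by Benjamini and Hochberg's method, and an adjusted p under 0.05 counted as past the threshold. All log2 changes are heterozygous minus wild-type, and all errors of changes are standard errors. The difference of genotype effects between bone and white adipose tissue was fitted with the animal as a block (consensus correlation -0.08, statmod 1.5.0). Effects in heart, which came from other animals, were compared with those in bone and white adipose tissue without a block. For these differences the 24 arrays were normalized together, and a probe had to be detected in at least 4 arrays of each tissue.

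Gene lists were written before the data were examined, as were the comparisons, the thresholds, most of the alternatives and the rule for naming genes. Tests of technical explanations were in part chosen, and bounds of some changed, after their results were seen. The 46 lists comprise 20 lists of cell type markers and 26 pathway or position lists. A position list holds genes within 10 Mb of Ednra. In each tissue 42 lists had at least 5 measured genes and were tested with limma's camera at its preset correlation of 0.01, adjusted over all 126 tests. Camera with a correlation estimated per list, and fry, were run as other tools. A list score is the mean over members of each gene's log2 level centred across the 8 arrays of a tissue, and scores were compared by two-sided exact permutation tests, whose smallest p for 4 against 4 arrays is 0.0286. Apart from the B cell list in bone, scores were tested only for lists that had passed camera on the same arrays. Their p-values are not adjusted for the number of lists and are not separate support for a list.

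The rule for naming genes took the measured endothelin signalling genes in each tissue, up to 12 genes per direction past the threshold, the 5 smallest p-values per direction where fewer than 5 genes passed, and up to 4 members of each list that passed and of the 22q11 and Ednra position lists. For differences between tissues it took 5 genes per direction.

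The alternatives were no background correction, an offset of 50, cyclic loess, scaling to the median, normalization of all 24 arrays together, no filter, detection at 0.01 in all 8 arrays, all probes, the authors' normalized intensities, no variance trend, array weights, a replicate block, adjusted p under 0.10, and each array left out in turn. Array brightness as a covariate, and median scaling for gene lists, were chosen after seeing the data. A further alternative left out both arrays that share a mouse number.

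The steps were tested on simulated data with genes changed by known folds. At 1.5-fold, 26.9% of 67 changed genes were recovered in heart, 71.6% in bone, 62.7% in white adipose tissue and 49.3% for the difference between bone and white adipose tissue. At 2-fold the shares were 47.8%, 98.5%, 83.6% and 79.1%, and at 4-fold they were 89.4%, 100%, 95.5% and 100%. Genes called without a simulated change numbered 11, 15, 13 and 14. A list shifted by 0.5 was recovered in each of the 3 tissues, with 1 other list called in each. Noise was simulated independently for each probe. The simulation therefore does not show how often lists of correlated genes are called without a shift.

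Probes with no gene symbol were kept out of the gene tests and tested apart. No probe was paired with Ednra or Tbx1, so these genes are not analysed here. Hybridization slides are not given in the sources used here, so no slide effect was fitted. The number of arrays limits the precision. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.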

Results

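Gene expression was compared between male C3HeB/FeJ mice heterozygous for a chemically induced allele of Ednra (Y129F) and wild-type mice, all 117 days old. Ednra encodes the type A endothelin receptor, and the study presents the line as a model of velocardiofacial and DiGeorge syndromes, which in patients usually follow a 22q11 deletion. There were 6 groups of 4 arrays, from heart, bone and white adipose tissue. The hearts came from 8 animals of their own. Bone and white adipose tissue came from shared animals, for which 7 mouse numbers are given because 1 number stands under both genotypes.

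Arrays detected 9931 to 12143 probes in heart, 13353 to 13919 in bone and 12956 to 13710 in white adipose tissue. The lowest value in heart belongs to wild-type array 4, and without it the lowest is 11467. With all 24 arrays normalized together, mean levels of tissue markers were highest in the tissue the labels give. The heart myosin Myh6 averaged 14.4 on the log2 scale in heart, 4.86 in bone and 4.52 in white adipose tissue, the osteocalcin gene Bglap2 averaged 14.1 in bone and reached 8.12 on 1 white adipose array, and the adipokine gene Adipoq averaged 14.1 in white adipose tissue and 10.7 in bone. Each of 3 Y-linked genes was detected on all 24 arrays and Xist on 0. Mean raw signal ran from 553 to 666 in heterozygous and from 702 to 820 in wild-type white adipose tissue, and from 433 to 477 and from 368 to 421 in heart, so in both tissues genotype and array brightness cannot be separated by these samples. No probe was paired with Ednra itself.

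In bone, the comparison asks whether transcript levels of the skeleton and its marrow differ with the receptor allele. The actin-severing protein gene Gsn rose 2.25-fold in heterozygous bone (log2 change 1.17, SE 0.181, adjusted p = 0.0429), from 7.24 ± 0.451 to 8.41 ± 0.111 (mean log2 level ± SD, n = 4 each). Bach1, a repressor of heme-responsive genes, fell 1.78-fold (log2 change -0.83, SE 0.107, adjusted p = 0.0287), from 9.12 ± 0.205 to 8.29 ± 0.0806. The RNA helicase gene Ddx6 fell 1.65-fold (log2 change -0.72, SE 0.0993, adjusted p = 0.0287), although its dimmer probes changed by -0.05 and -0.29. Purb, for a single-stranded DNA binding protein, fell 1.77-fold (log2 change -0.83, SE 0.125, adjusted p = 0.0429).

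The other genes that rose in bone were the stefin family gene Csta3, the gene AB124611 and the growth regulator gene Slfn1. Csta3 rose 1.98-fold (log2 change 0.99, SE 0.158, adjusted p = 0.0429) and was detected on 2 of 4 wild-type arrays. AB124611 rose by 0.94 (SE 0.151, adjusted p = 0.0429) and Slfn1 by 0.58 (SE 0.0938, adjusted p = 0.0429), the latter from 9.47 ± 0.143 to 10.1 ± 0.129. These 7 genes, 4 higher and 3 lower, are the whole set past the threshold among 9460, while 1746 genes had an unadjusted p under 0.05 (763 higher, 983 lower). The groups showed no overlap for 934 genes, or 9.87%, against an average of 2.86% over all splits of the arrays. Genes vary together, so 1 split can exceed that average without an effect of genotype. The share in other splits was not counted.

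The bone result rests on which arrays are in it. Without wild-type array 3, 803 genes passed (417 higher, 386 lower), among them Gsn, Bach1 and all of the other 5, with adjusted p between 0.000612 and 0.00594. Without wild-type array 4, 3 genes passed, including Csta3 and Bach1, and with any of the other 6 arrays left out 0 passed. The plot of gene counts with each array left out shows these numbers beside those of white adipose tissue.

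**Figure D1:**
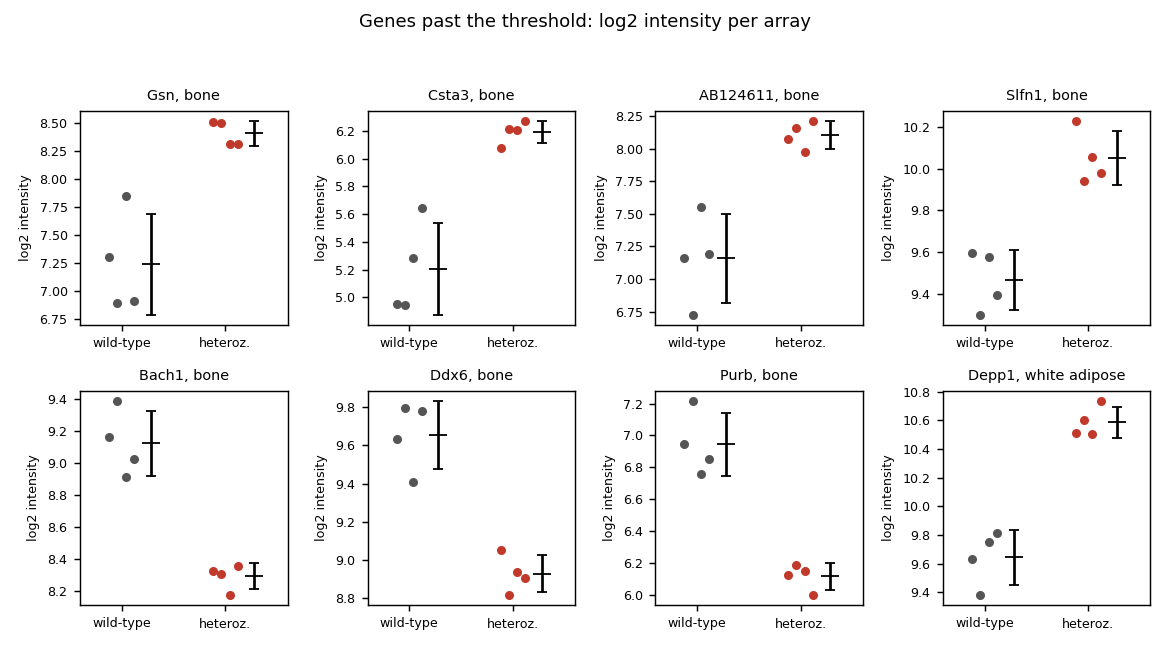
Log2 intensity (vertical axis) of the 7 genes past the threshold in bone and of Depp1 in white adipose tissue, with a dot per array (grey wild-type, red heterozygous) and bars for mean ± SD, n = 4 per group. In each panel the groups are apart, as for Gsn at 7.24 ± 0.451 and 8.41 ± 0.111.

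Bone also expressed most of the endothelin pathway. The G protein gene Gna13 had a log2 change of -0.40 (SE 0.0905, adjusted p = 0.0679) and Ece1, for the enzyme that activates endothelin, -0.63 (SE 0.195, adjusted p = 0.118), with a dimmer Ece1 probe at -0.04. Prkca changed by -0.32, Gna12 by 0.46, the type B receptor gene Ednrb by 0.32 and the ligand gene Edn1 by -0.22, none past the threshold. Gnaq lay at -0.09 with another probe at 0.43, Ece2 at 0.16, Gna11 at 0.05, Plcb3 at 0.01 and Plcb4 at -0.00. The sign of Gna11 turned without wild-type array 2 (-0.02), that of Plcb3 without wild-type array 4 (-0.05), and that of Plcb4 without wild-type array 3 (0.14) and under median scaling (0.04). As a list of 11 genes, endothelin signalling gave adjusted p = 0.699 in camera, with 0 members past the threshold over all genes (limma; 4 members had unadjusted p under 0.05) and 2 lower when adjusted over the list alone.

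Marrow cell lists moved in different directions in bone. The neutrophil and granulocyte list was shifted up (median log2 change 0.36, 22 of 23 members higher, camera adjusted p = 3.44e-10; adjusted p = 0.81 with an estimated correlation). Its scores averaged 0.19 ± 0.115 in heterozygous and -0.19 ± 0.252 in wild-type arrays (SD, n = 4 each, exact permutation p = 0.0286). Score tests of passing lists, here and below, used the same arrays that had picked the lists, so they are not separate support. Members include Retnlg at 0.57 (SE 0.112), Ms4a3 at 0.77 (SE 0.159, another probe at 0.35), and the stefins Stfa1 at 1.13 (SE 0.277) and Stfa2 at 0.93 (SE 0.242). None of the 23 passed over all genes, 15 were higher when adjusted over the list alone, and 11 passed over all genes without wild-type array 3.

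The macrophage list in bone was shifted up as well (median 0.38, 15 of 16 members higher, camera adjusted p = 1.71e-06; adjusted p = 0.81 with an estimated correlation). Lyz2, for lysozyme, changed by 0.50 (SE 0.131), Ms4a7 by 0.61 (SE 0.173), the lipopolysaccharide receptor gene Cd14 by 0.53 (SE 0.152) and the complement gene C1qc by 0.52 (SE 0.152). Of its 16 members, 10 were higher when adjusted over the list alone and 0 over all genes, or 7 without wild-type array 3. Scores averaged 0.17 ± 0.0833 and -0.17 ± 0.193 in heterozygous and wild-type arrays (n = 4 each, exact permutation p = 0.0286).

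The erythroid list was shifted down (median -0.24, 11 of 14 members lower, camera adjusted p = 0.0112; adjusted p = 0.81 with an estimated correlation, and 0.0909 with a median of -0.14 without heterozygous array 1). Its scores gave exact permutation p = 0.0571 (n = 4 each). Gata1, a master regulator of red cell genes, changed by -0.46 (SE 0.126) with another probe at 0.01, the blood group gene Kel by -0.38 (SE 0.107), the heme synthesis gene Alas2 by -0.26 (SE 0.0757) and the transferrin receptor gene Tfrc by -0.29 (SE 0.0878). Adjusted over the list alone 7 members were lower, against 0 over all genes and 4 without wild-type array 3. The B cell list (median -0.19, adjusted p = 0.0711), the osteoblast list (median -0.05, adjusted p = 0.63) and the osteoclast list (median -0.06, adjusted p = 0.958) did not pass.

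Among pathway lists in bone, acute inflammation was shifted up (median 0.24, 14 of 19 members higher, camera adjusted p = 0.00146), led by Orm1 at 0.77 (SE 0.174), Hp at 0.46 with other probes at 1.05 and 1.03, Ccl9 at 0.31 and Nfkbia at 0.25. Heat shock genes were shifted down (median -0.19, 15 of 18 lower, adjusted p = 0.00499, or 0.0728 without heterozygous array 4), with Chordc1 at -0.45 (SE 0.0871), Hsph1 at -0.63 (SE 0.15), Fkbp4 at -0.23 and Hspd1 at -0.25, whose other probe lay at 0.35. Antigen presentation by MHC class II was shifted up (median 0.21, 9 of 10 higher, adjusted p = 0.0178, or 0.0658 without wild-type array 2), with H2-Ea at 0.37, H2-Eb1 at 0.31, H2-DMa at 0.30 and Cd74 at 0.28. The interferon list was shifted up (median 0.14, 19 of 26 higher, adjusted p = 0.03), with Psmb8 at 0.47, Ifit2 at 0.37, Ifit3 at 0.42 and Gbp2 at 0.39. It was lost without wild-type array 1 (0.148, median 0.06), wild-type array 3 (0.13), heterozygous array 2 (0.256, median 0.09) or heterozygous array 3 (0.0885, median 0.08). Each of these 4 lists had adjusted p = 0.81 with an estimated correlation. Their scores gave exact permutation p = 0.0857 for inflammation, 0.171 for heat shock, 0.0571 for MHC class II and 0.257 for interferon (n = 4 each). Members past the threshold when adjusted over the list alone numbered 3 for inflammation, 2 for heat shock, 0 for MHC class II and 1 for interferon, and over all genes 0 for each, while without wild-type array 3 inflammation had 4 higher and 1 lower, heat shock 4 lower, MHC class II 2 and interferon 1. Without that array 803 of all 9375 genes passed, so 1 interferon gene of 25 is no excess.

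The lists tied to the disease model did not pass in bone. Mouse homologues of 22q11 deletion region genes had a median of -0.06 over 22 genes (adjusted p = 0.353), with Tango2 at -0.18, Dgcr8 at -0.27, Gp1bb at -0.21 and Mrpl40 at 0.19, and 0 of them were past the threshold when adjusted over the list alone. Genes near Ednra had a median of -0.06 over 134 genes (adjusted p = 0.699). Tom1 among them changed by 0.83 (SE 0.169, adjusted p = 0.0679) and was the 1 gene past the threshold when adjusted over the list alone, while Sugp2 lay at -0.34, Cyp4f18 at 0.36 (other probes at 0.89 and 0.29) and Nacc1 at -0.44 (another probe at -0.19).

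In white adipose tissue, the comparison asks the same of fat. Depp1, a fasting-induced regulator of autophagy, rose 1.92-fold in heterozygous tissue (log2 change 0.94, SE 0.102, adjusted p = 0.0297), from 9.64 ± 0.192 to 10.6 ± 0.109 (SD, n = 4 each). It was the 1 gene past the threshold among 9292, while 2748, or 29.6%, had an unadjusted p under 0.05 (1448 higher, 1300 lower) and 1464 an adjusted p under 0.10. With so large a share, adjustment over a list alone yields calls in many lists of this tissue. With the replicate number of the labels as a block 1306 passed (649 higher, 657 lower), Depp1 among them. Groups showed no overlap for 1544 genes, or 16.6%, against an average of 2.86% over all splits, but this split also divides the arrays by brightness. Next in order of p among genes with higher means were Eif3k at 0.59 (SE 0.0843), Etfb at 0.34 (SE 0.0504), Tmem150a at 0.64 (SE 0.0963, another probe at 0.14) and Fam13a at 1.61 (SE 0.25, adjusted p = 0.0573). Those with lower means were Trp53inp2 at -0.69 (SE 0.0961), Htra3 at -0.36 (SE 0.0503, another probe at -0.65), Mex3c at -1.14 (SE 0.163, detected on 3 of 4 heterozygous arrays), Rbm28 at -0.66 (SE 0.0969) and the clotting factor gene F13a1 at -0.41 (SE 0.0599, adjusted p = 0.0546).

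The number of genes past the threshold in white adipose tissue varied with the arrays. It was 851 without wild-type array 3 (470 higher, 381 lower) and 1156 without wild-type array 4 (548 higher, 608 lower), with 511 genes in both sets, 1 without wild-type array 2 and 0 with any of the other 5 left out. Depp1 kept its call without wild-type array 2, 3 or 4 (adjusted p = 0.0367, 0.0268 and 0.0277) and lost it without wild-type array 1 (0.0826) or any heterozygous array (0.074 to 0.149). With array brightness as a covariate its change was 0.82 (adjusted p = 0.973), and 0 genes passed by limma, with 336 at unadjusted p under 0.05.

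**Figure D2:**
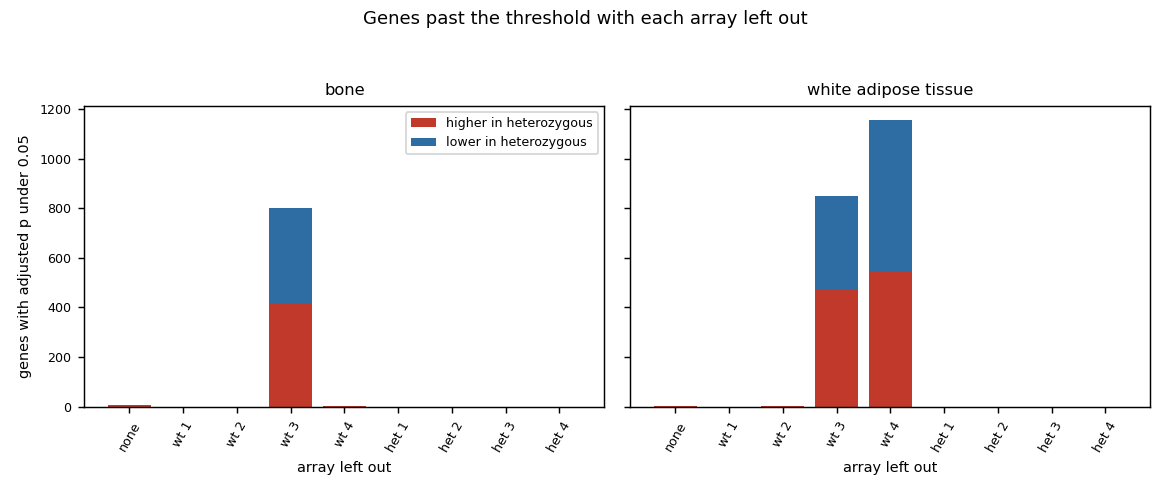
Number of genes with adjusted p under 0.05 (vertical axis) with no array or each single array left out (horizontal axis) in bone and white adipose tissue, with red for genes higher and blue for genes lower in heterozygous arrays. Counts reached 803 in bone without wild-type array 3, and 851 and 1156 in white adipose tissue without wild-type array 3 or 4.

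The macrophage list in white adipose tissue was shifted down, opposite to bone (median -0.59, all 15 members lower, camera adjusted p = 4.04e-06; adjusted p = 0.81 with an estimated correlation). The fractalkine receptor gene Cx3cr1 changed by -0.85 (SE 0.194), the mannose receptor gene Mrc1 by -0.57 (SE 0.131), Lyz2 by -1.01 (SE 0.244, another probe at -0.43) and C1qc by -0.48 (SE 0.116). Scores averaged -0.35 ± 0.114 in heterozygous and 0.35 ± 0.542 in wild-type arrays (n = 4 each, exact permutation p = 0.0286), but the wild-type group is split, with macrophage scores of 0.91 and 0.72 on wild-type arrays 1 and 2 and -0.09 and -0.14 on wild-type arrays 3 and 4. Over all genes, on an axis from the wild-type mean (0) to the heterozygous mean (1) built without the array placed, these 4 scored -0.763, -0.300, 0.575 and 0.776, and heterozygous arrays 0.598 to 1.22. Even with no genotype effect, a left-out wild-type array tends past the middle of such an axis, since fewer arrays then set the wild-type end. Adjusted over the list alone 11 members were lower, against 0 over all genes, 8 without wild-type array 4 and 4 without wild-type array 3. Those 2 wild-type arrays lie nearest the heterozygous ones on that axis, so leaving either out widens the difference. With both arrays that share a mouse number left out, 0 members passed over all genes in any of the 6 lists that passed in white adipose tissue.

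Acute inflammation was shifted down too in white adipose tissue (median -0.61, 13 of 17 members lower, camera adjusted p = 0.0016), with the chemokine gene Ccl8 at -0.70 (SE 0.112), Orm1 at -0.67 (SE 0.127), Hp at -0.28 (SE 0.0684, other probes at -0.72 and -0.76) and the serum amyloid gene Saa3 at -1.96 (SE 0.522). The inflammation median was -0.37 without wild-type array 1 (adjusted p = 0.00374) and -0.38 without wild-type array 2 (0.00846). Antigen presentation by MHC class II had all 8 measured members lower (median -0.60, adjusted p = 0.0132, or 0.0572 without wild-type array 2, and median -0.40 without wild-type array 1), with H2-DMa at -0.75, Ciita at -0.90, H2-DMb1 at -0.66 and Cd74 at -0.48. Cell division genes were shifted down (median -0.36, 20 of 21 lower, adjusted p = 0.000574), with Kif23 at -0.63, Prc1 at -0.72, Cdk1 at -0.82 and Top2a at -0.87. All 3 lists had adjusted p = 0.81 with an estimated correlation. Exact permutation of their scores gave p = 0.0571 for inflammation, 0.2 for MHC class II and 0.114 for cell division (n = 4 each). Adjusted over the list alone, inflammation had 10 members lower and 1 higher, MHC class II 0 and cell division 0, and over all genes each had 0, against 9, 3 and 1 without wild-type array 4 and 3 for inflammation without wild-type array 3. Without wild-type array 4, 1156 of all 9156 genes passed, so 1 cell division gene of 20 is no excess. With brightness as a covariate the medians of MHC class II and cell division turned to 0.28 and 0.09.

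The fibrillar collagen and matrix list was shifted down in white adipose tissue (median -0.34, 17 of 22 members lower, camera adjusted p = 0.000574; adjusted p = 0.81 with an estimated correlation). Fbln2 changed by -0.44 (SE 0.0934, other probes at -0.93 and -0.25), the collagen-binding gene Lum by -0.95 (SE 0.234), the protease inhibitor gene Timp1 by -0.98 (SE 0.244) and Col6a1 by -0.62 (SE 0.157, other probes at -1.43 and -0.52). Adjusted over the list alone 13 were lower and 2 higher, and over all genes 0, or 2 higher and 8 lower without wild-type array 4 and 5 without wild-type array 3. Oxidative phosphorylation was shifted up (median 0.16, 31 of 36 members higher, adjusted p = 0.000786; adjusted p = 0.81 with an estimated correlation), with Atp5g1 at 0.32 (SE 0.0591), Sdhb at 0.31 (SE 0.0619), Atp5d at 0.27 (SE 0.0572) and Ndufs7 at 0.46 (SE 0.112). Of its members 10 were higher when adjusted over the list alone, 0 over all genes, and 9 without wild-type array 3 as well as 9 without wild-type array 4. Score tests gave exact permutation p = 0.0286 for both lists (n = 4 each). With brightness as a covariate the oxidative phosphorylation median was 0.04 (adjusted p = 0.354), and without heterozygous array 2, which carries muscle transcripts, it was 0.19 (0.000355). The skeletal muscle list (median 0.98, 9 of 10 higher, adjusted p = 0.163) and the mesothelium list (median 0.36, 10 of 10 higher, adjusted p = 0.0819) moved up in the same tissue without passing.

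**Figure D3:**
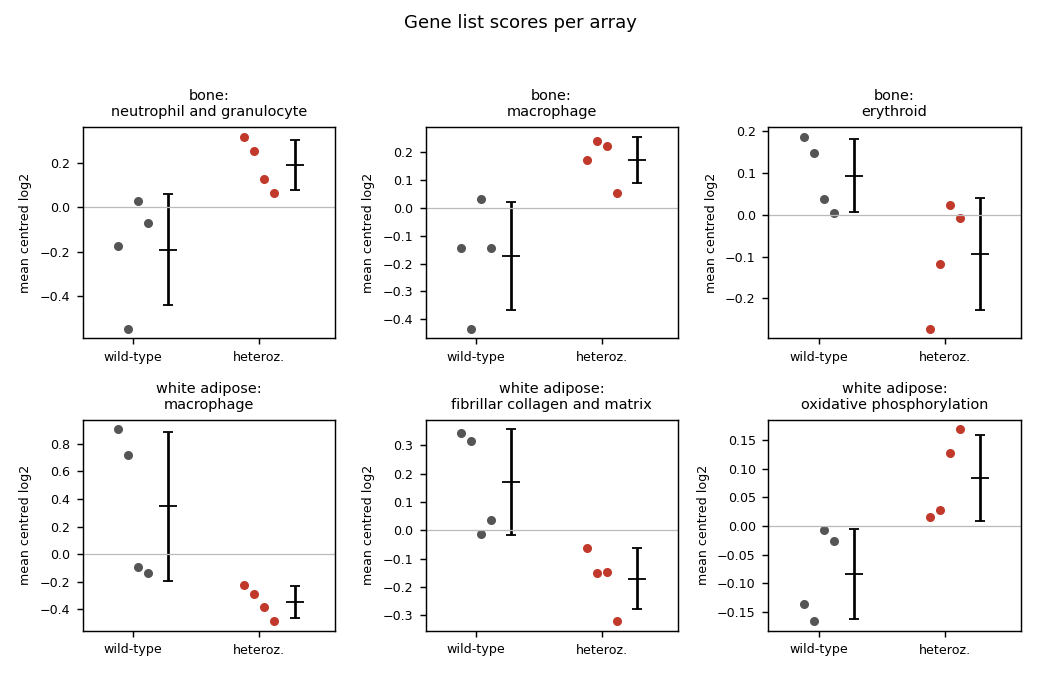
List score (vertical axis, mean centred log2 level of the members) per array for 3 lists in bone and 3 in white adipose tissue, with dots for arrays (grey wild-type, red heterozygous) and bars for mean ± SD, n = 4 per group. Macrophage scores lie higher in heterozygous bone (0.17 ± 0.0833 against -0.17 ± 0.193) and lower in heterozygous white adipose tissue (-0.35 ± 0.114 against 0.35 ± 0.542).

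Endothelin signalling genes in white adipose tissue included Gna12 at -0.61 (SE 0.181, adjusted p = 0.0787), Prkca at -0.42 (SE 0.132), Gna11 at 0.20 (SE 0.0667), Gna13 at 0.35 (SE 0.145) and Edn1 at 0.28 (SE 0.136). Ece1 lay at -0.13 with another probe at 0.35, Plcb3 at 0.13, Gnaq at -0.12 with another probe at -0.30, Ece2 at -0.13, Plcb4 at -0.03 and Ednrb at 0.02 with other probes at -0.51 and 0.05. Ednrb turned to -0.0022 under cyclic loess and Plcb4 to 0.04 under median scaling. The list of 11 had adjusted p = 0.773 in camera, 0 members past the threshold over all genes and 0 over the list alone (limma; 4 had unadjusted p under 0.05). The 22q11 list did not pass (median 0.05 over 22 genes, adjusted p = 0.344), with Dgcr6 at 0.42 (adjusted p = 0.0647), Slc25a1 at 0.36, Txnrd2 at 0.32 (another probe at 0.15) and Gnb1l at 0.40, and 5 members were higher when adjusted over the list alone. At unadjusted p under 0.05 in limma, 6 of its 22 genes were higher and 1 lower, near the share of 29.6% among all genes of this tissue. Genes near Ednra did not pass either (131 genes, adjusted p = 0.773), with Scoc at -0.55 (adjusted p = 0.0598, another probe at 0.19), Slc27a1 at 0.88, Ell at 0.39 and Zfp423 at -0.38, and 0 over the list alone.

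In heart, the comparison asks whether the allele changes adult heart muscle, an organ often malformed in the syndromes. Among genes with the smallest p-values, the stress kinase gene Sgk1 had a log2 change of 0.60 (SE 0.116), at 10.8 ± 0.168 in heterozygous and 10.2 ± 0.16 in wild-type hearts (SD, n = 4 each). The natriuretic peptide gene Nppb, a marker of wall stress, lay at 12.7 ± 0.192 and 12.2 ± 0.127 (log2 change 0.53, SE 0.107). The iron regulator gene Hamp lay at 8.97 ± 0.492 and 10.1 ± 0.148 (log2 change -1.12, SE 0.226). Each had adjusted p = 0.608. By limma 0 of 8535 genes passed, 472 had an unadjusted p under 0.05 (146 higher, 326 lower), and 1 passed without heterozygous array 2. On an axis built in the same way as for white adipose tissue, heart wild-type arrays 1 to 3 scored 0.714 to 0.812, among the heterozygous arrays (0.672 to 1.03), and wild-type array 4 scored -1.10. For arrays 1 to 3 the wild-type end of this axis includes wild-type array 4, which lacks signal for many transcripts. Their scores therefore do not show that these hearts resemble heterozygous ones. Groups showed no overlap for 685 genes, or 8.03%, against an average of 2.86% over all splits, which 1 split can exceed without an effect of genotype. The median change of all genes was -0.09 with quantile scaling and 0.01 with cyclic loess.

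Others with small p-values in heart were Erdr1 at 1.18 (SE 0.212, detected on 2 of 4 wild-type arrays), Tbc1d22b at 1.17 (SE 0.219, detected on 1 of 4), Ppp2r5a at 1.10 (SE 0.225), Art5 at -0.43 (SE 0.105), Eif4ebp1 at -0.40 (SE 0.0983), Ascc1 at -0.60 (SE 0.15, another probe at 0.12) and Tbc1d10b at -0.59 (SE 0.151, detected on 2 of 4 heterozygous arrays). Endothelin signalling had 9 measured genes (camera adjusted p = 0.0993, 0 past the threshold over the list alone and 0 over all genes by limma, 0 at unadjusted p under 0.05). Gna11 lay at 0.91 (SE 0.493), Edn1 at 0.49 (SE 0.427), Ece1 at 0.49 (SE 0.492), Plcb4 at 0.37 (SE 0.243), Ece2 at 0.20, Gnaq at -0.15, Plcb3 at -0.11, Prkca at 0.04 and Ednrb at 0.01 with another probe at -0.12. Plcb3 turned to 0.02 under cyclic loess and Ednrb to -0.05 under median scaling. Without wild-type array 4, which lacks signal for many transcripts, Gna11 lay at 0.32, Edn1 at 0.02, Ece1 at -0.08, Plcb4 at 0.61 and Ece2 at 0.06.

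Of the heart lists, immediate early genes were shifted up (median 0.31, 15 of 17 members higher, camera adjusted p = 7.89e-05), with Klf2 at 0.31 (SE 0.102), Fos at 1.20 (SE 0.493), Junb at 0.85 (SE 0.437) and Atf3 at 0.34 (SE 0.174). The immediate early score of wild-type array 4 was -0.57, against -0.09 to -0.03 on the other wild-type arrays, and without it the median was 0.27 (adjusted p = 0.000789) and Junb lay at 0.36. The fibrillar collagen and matrix list was shifted up (median 0.14, 14 of 19 higher, adjusted p = 0.00427), with Lox at 0.82, Eln at 0.35, Tnc at 0.36 and Col1a1 at 0.88, and was lost without heterozygous array 4 (0.387, median 0.03, Col1a1 0.53, Lox 0.46) or wild-type array 4 (0.0647, Col1a1 0.39). Its median was 0.25 without heterozygous array 2 and 0.33 without heterozygous array 3. The glucocorticoid and fasting list was shifted up (median 0.12, 10 of 17 higher, adjusted p = 0.0123), with Pdk4 at 0.37, Cdkn1a at 0.46 (other probes at 0.52 and 1.43) and Errfi1 at 0.53 beside Sgk1, and was lost without heterozygous array 4 (0.133, median -0.03) or wild-type array 3 (0.07). Cytosolic ribosome genes passed as well (median 0.06, 22 of 36 higher, adjusted p = 0.0225), with Rpl34 at 0.16, Rpl24 at 0.55, Rpl23 at -0.16 (other probes at -0.02 and -0.29) and Rplp1 at 0.14, but under median scaling the list turned to -0.08 and Rplp1 to -0.06, and it was lost without heterozygous array 4 (0.0952) or wild-type array 4 (0.0941, median 0.03, Rpl24 0.23). Scores gave exact permutation p = 0.0286 for immediate early genes, 0.229 for collagen and matrix, 0.171 for glucocorticoid genes and 0.0571 for ribosome genes (n = 4 each). All 4 lists had adjusted p = 0.81 with an estimated correlation and 0 members past the threshold over all genes, and 2 glucocorticoid genes were higher when adjusted over the list alone, against 0 in the others.

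The mesothelium list, genes of the lining of the heart's outer surface, was shifted down in heart (median -0.58, 6 of 8 members lower, camera adjusted p = 0.0466; adjusted p = 0.81 with an estimated correlation). Upk1b changed by -1.14 (SE 0.319), Msln by -1.05 (SE 0.299) and Krt8 by -0.54 (SE 0.231), and 2 members were lower when adjusted over the list alone, 0 over all genes. Krt18 was detected on 0 of 4 heterozygous arrays and was at least 1.47-fold higher in wild-type hearts, against the detection floor (adjusted p = 0.608), or 1.18-fold without wild-type array 4. Its scores gave exact permutation p = 0.0286 (n = 4 each). The list was lost without wild-type array 1 (0.231), 2 (0.0856), 3 (0.07) or 4 (0.0579). The 22q11 list did not pass (19 genes, median -0.07 although the test pointed up, adjusted p = 0.773), with Slc25a1 at -0.30, Crkl at 0.49, Thap7 at -0.37 and Mrpl40 at 0.31, and neither did genes near Ednra (122 genes, median -0.11 although the test pointed up, adjusted p = 0.964), with Arhgap10 at 1.02 (SE 0.275, another probe at 0.55), Nr2c2ap at -0.51 and Fkbp8 at -0.29. Both lists had 0 members past the threshold over the list alone.

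The last comparison asks whether the allele acts alike in the tissues. Between bone and white adipose tissue the genotype effect differed for 964 of 8508 genes (474 with the higher effect in bone, 490 in white adipose tissue). Array brightness follows genotype in white adipose tissue and was not fitted in this test, so an effect of the allele cannot be separated from brightness there. Bach1 changed by -0.86 in bone and 0.63 in white adipose tissue (difference -1.49, SE 0.198, adjusted p = 0.00571). The mRNA regulator gene Mex3c changed by 0.43 and -0.96 (difference 1.39, SE 0.205, adjusted p = 0.006), and Orm1 by 0.80 and -0.78 (difference 1.58, SE 0.262, adjusted p = 0.0114). Wfdc17, an antimicrobial peptide gene of myeloid cells, changed by 1.30 and -0.92 (difference 2.23, SE 0.378, adjusted p = 0.0114). Ddx6 had a difference of -1.26 (SE 0.187), Purb -1.38 (SE 0.232), Med12 -1.12 (SE 0.182), Sdcbp2 -0.97 (SE 0.16), Tmem38b 0.97 (SE 0.144) and Tiam1 0.76 (SE 0.128).

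That count moved with the animals. It was 0 without wild-type animal 2, where all 10 named genes were lost (adjusted p 0.0635 to 0.0741), and 8 without wild-type animal 1, where Orm1, Tiam1, Wfdc17 and Sdcbp2 were lost (0.0536 to 0.0558). It was 16 without heterozygous animal 2, where Tiam1 was lost (0.0507), 151 without heterozygous animal 3, 206 without heterozygous animal 4 and 425 without heterozygous animal 1, and it reached 1972 without wild-type animal 3, with 951 shared genes. The macrophage list differed between bone and white adipose tissue (median effects 0.40 and -0.57, adjusted p = 1.11e-07; adjusted p = 0.666 with an estimated correlation).

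Between heart and bone the effect differed for 0 of 7929 genes by limma, with 593 at unadjusted p under 0.05 and 8 without heart wild-type array 4. Between heart and white adipose tissue it differed for 0 of 7936, with 1778 at unadjusted p under 0.05, 522 without heart wild-type array 4 and 70 without white adipose wild-type array 3. Immediate early genes differed between heart and bone (median difference 0.47, adjusted p = 0.000276; adjusted p = 0.509 with an estimated correlation), and collagen and matrix genes differed between heart and white adipose tissue (median difference 0.58, adjusted p = 0.00069; adjusted p = 0.666 with an estimated correlation). Brightness follows genotype in heart and in white adipose tissue and was not fitted in these tests either.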

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

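The 4 tests of bone wild-type array 3, the test for more marrow in heterozygous bone and the test for a bias that depends on signal level were chosen only after the results they address were seen. After a first run the brightness test among them replaced one that could hardly fail, since raw signal of that array (mean 568.5) lies just under the other wild-type arrays (571.1 to 625.4) and near the heterozygous mean of 564. Also after that run, the bound for the white adipose test was narrowed by dropping a clause on other wild-type arrays, and the test for 1 animal under both labels was added. Later, with all values known, the bound of that last test was widened to the spread of array pairs, and the marrow test was moved from the erythroid list, which is part of the pattern, to the B cell list. The tests on other splits of the arrays, on lost probes and on a wrong tissue were chosen before.

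Bone wild-type array 3 lies near the heterozygous arrays. On an axis from the wild-type mean (0) to the heterozygous mean (1), built without it, the array scored 0.749, against -0.326 to 0.257 for the other wild-type arrays and 0.68 to 0.855 for the heterozygous arrays. Array brightness is argued against by the score of 0.0767 of the wild-type array nearest in raw signal. For 1 animal sampled under both labels of the doubled mouse number, which cannot be told apart from separate animals, the bone array correlates at 0.996 with heterozygous array 4, whose closest array it is, and at 0.997 with heterozygous array 3, while its white adipose partner correlates least with heterozygous array 4 of that genotype (0.994 against up to 0.997, a gap of 0.00332 where pairs have an SD of 0.00545). A heterozygous animal under a wild-type label is a candidate explanation from bone, but in white adipose tissue it cannot be told apart from spread between animals. The same animal scored 0.575 there and wild-type array 4 scored 0.776, and variation between wild-type animals was not tested. Even with no genotype effect, a left-out wild-type array tends past the middle of this axis, since fewer arrays then set the wild-type end. The score of 0.575 therefore does not bear on the label of that animal.

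Heart wild-type array 4 lacks signal for many transcripts. Its median correlation with the other heart arrays on raw log2 intensities was 0.927, against 0.993 to 0.995 elsewhere, and 597 genes lay more than 2 log2 units below the mean of the other arrays, such as Rps2 at 4.50 against 12.35, where other arrays had 0 to 8 such genes. A sample of another tissue is argued against by its median correlation with the heart arrays (0.91 across probes after normalization), above those with bone (0.781) and white adipose tissue (0.782). Of 8846 probes detected on the other 7 arrays it lost 1203, and a second probe of the same gene was lost in 26.1% of cases against a base rate of 18.5%, which may point to loss of single probes on this array rather than of transcripts. A biological difference of this animal was not tested.

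In bone the granulocyte and macrophage lists were higher and the erythroid list lower in heterozygous arrays. More marrow in the heterozygous samples cannot be told apart from an unchanged amount by the B cell list, whose median was -0.19 (exact permutation p = 0.171 for its scores, n = 4 each). The granulocyte median was 0.36, while the central 95% of 10000 random lists of matched signal lay between -0.09 and 0.05. This argues only against a bias shared by genes of that signal level. The list was picked because it had already passed. The random lists hold genes drawn independently, whereas the estimated correlation in this list is 0.475, so their range is too narrow to judge chance. A shift in amount or composition of marrow with genotype may remain as a hypothesis, and with an estimated correlation between genes these lists did not pass. The granulocyte list shares 1 gene with the glucocorticoid list and the macrophage list 1 with MHC class II.

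Counts were set against other splits of the same arrays into 4 and 4. In bone 1 of 35 splits, the real one, gave as many as its 7 genes, and the highest other gave 1. A share of 1 in 35 is the smallest this test can give. It makes chance a less likely source of the count but does not exclude it. In white adipose tissue 1 of 35 splits gave as many as the real 1 gene, and the highest other gave 0. In heart the real count was 0, which any split meets (35 of 35, the highest other being 0), so no conclusion follows from it. For lists adjusted within a tissue, chance is not excluded in any tissue. In heart 24 of 35 splits gave at least the real 4 (highest other 12), in bone 24 of 35 at least the real 7 (highest other 21) and in white adipose tissue 16 of 35 at least the real 6 (highest other 12). The cause was not tested. Estimated correlations within the 18 passing lists run from 0.0102 to 0.893, above the preset 0.01, and 0 lists passed with them. For bone against white adipose tissue 1 of 35 splits of the animals gave as many as 964 genes, with 110 in the highest other. The real split also divides the white adipose arrays by brightness, so this test cannot tell genotype from brightness. For heart against bone and heart against white adipose tissue the real count of 0 was met by 100 of 100 drawn splits, the highest others giving 0 and 3. Any split meets a count of 0, so these outcomes were fixed in advance.

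Single arrays were compared with the other 3 of their group, and an array stands out when its gap to the nearest, as a ratio to the group's range, exceeds the 95% critical value of Dixon's test. Chance alone does this in about 1 in 20 groups. It happened in 3 of 18 array measures, 3 of 36 list scores and 30 of 304 gene groups, with 10 of the gene groups, 2 of the list scores and 1 of the measures on heart wild-type array 4. The array measures were mean raw signal of heart heterozygous array 1 (ratio 0.94), median correlation of heart wild-type array 4 (0.969) and probes detected on bone heterozygous array 4 (0.841). Scores were those of immediate early genes (0.886) and ribosome genes (0.984) on heart wild-type array 4 and of glucocorticoid genes on heart heterozygous array 4 (0.948).

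On heart wild-type array 4 the genes that stood apart were Gna11 (0.964), Plcb4 (0.902), Ece1 (0.881), Rpl24 (0.834), Col1a1 (0.875), Junb (0.885), Krt18 (0.872), Mrpl40 (0.903), Ppp2r5a (0.862) and Ascc1 (0.9). Elsewhere in heart these were Ece1 (0.869), Rplp1 (1, where the other 3 arrays tie) and Mrpl40 (0.902) on heterozygous array 1, Ppp2r5a (0.864) on heterozygous array 2, Col1a1 (0.935) on heterozygous array 4, Klf2 (0.83) on wild-type array 1, and Lox (0.884) and Slc25a1 (0.854) on wild-type array 2. In bone, all on heterozygous arrays, they were Gata1 (0.844) on array 1, Gbp2 (0.853) on array 2, Stfa1 (0.955) on array 3, and Gnaq (0.879) and Mrpl40 (0.861) on array 4. In white adipose tissue they were Plcb3 (0.84), Plcb4 (0.895), Txnrd2 (0.847) and Ndufs7 (0.845) on heterozygous array 2, Gna12 (0.834) and Fbln2 (0.881) on heterozygous array 4, and Ece2 (0.896) on wild-type array 4.

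Effects of genotype differed between bone and white adipose tissue, by a test of the difference itself, for 964 genes, 0 without wild-type animal 2 and 1972 without wild-type animal 3. Brightness was not fitted in this test. In white adipose tissue it cannot be separated from genotype, and 0 genes passed there with brightness as a covariate. Differences of effect were 1.39 for Mex3c, 0.97 for Tmem38b, 1.58 for Orm1, 0.76 for Tiam1, 2.23 for Wfdc17, -1.49 for Bach1, -1.26 for Ddx6, -1.12 for Med12, -0.97 for Sdcbp2 and -1.38 for Purb. Lists differed by a median of 1.04 for macrophage, 0.74 for MHC class II, 0.52 for inflammation, 0.28 for cell division and -0.21 for oxidative phosphorylation. With an estimated correlation in camera none of them passed (adjusted p 0.67 to 0.82). Cell division was lost without heterozygous animal 3 (adjusted p = 0.0776) or 4 (0.0684), and oxidative phosphorylation without wild-type animal 2 (0.0897) or 4 (0.0793) or heterozygous animal 3 (0.293) or 4 (0.113).

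Between heart and bone, list effects differed by 0.47 for immediate early genes, 0.40 for collagen and matrix, 0.26 for the contractile apparatus, 0.21 for heat shock and -0.34 for interferon. Collagen and matrix was lost without heart heterozygous array 4 (adjusted p = 0.115). Heat shock was lost without heart wild-type array 1 (0.129), bone wild-type array 1 (0.0513) or bone heterozygous array 4 (0.114). The contractile apparatus was lost without heart wild-type array 4 (0.202), bone wild-type array 1 (0.0803) or 2 (0.0906) or bone heterozygous array 3 (0.0565). Interferon was lost without heart heterozygous array 1 (0.0549), 2 (0.148) or 3 (0.0718), heart wild-type array 4 (0.232), bone wild-type array 1 (0.0948) or bone heterozygous array 2 (0.115) or 3 (0.0633). Between heart and white adipose tissue they differed by 0.58 for collagen and matrix, 0.34 for immediate early genes, 0.75 for macrophage, 0.58 for inflammation, -1.11 for mesothelium, -0.21 for oxidative phosphorylation and 0.39 for osteoclast. Inflammation was lost without heart heterozygous array 4 (0.0866), and mesothelium without each heart wild-type array (0.0757 to 0.211). Oxidative phosphorylation was lost without heart heterozygous array 4, heart wild-type array 1, 2 or 3, or white adipose wild-type array 2 or heterozygous array 4 (0.0586 to 0.166). Osteoclast was lost without heart heterozygous array 4, each heart wild-type array, white adipose wild-type array 1 or 2, or white adipose heterozygous array 1, 3 or 4 (0.0509 to 0.162). None of these list differences passed with an estimated correlation. Outside the gene tests, probes with no gene symbol passed the threshold in 7 of 792 cases in bone and 11 of 763 in white adipose tissue (heart by limma 0 of 654, with 33 at unadjusted p under 0.05).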

How the results depend on the processing

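Array brightness as a covariate and median scaling of gene lists were chosen after seeing the data, and the other alternatives here were planned. A slide block was not run, since slides are not given in the sources used here, and leaving out the animal block does not apply to comparisons with heart.

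The count of 7 genes in bone became 14 with no background correction, 12 with an offset of 50, 21 with median scaling (16 higher, 5 lower), 49 with all 24 arrays normalized together, 3 with no filter, 2 with all probes, 14 with the authors' normalized values, 541 with array weights and 336 at adjusted p under 0.10. With no variance trend or with brightness as a covariate it became 0 in limma, while 1699 and 1736 genes had an unadjusted p under 0.05. The count of 1 in white adipose tissue became 369 with all 24 arrays together, 162 with detection in all 8 arrays, 1653 with array weights and 1464 at adjusted p under 0.10, and 0 in limma with no variance trend or brightness as a covariate, while 2621 and 336 genes had an unadjusted p under 0.05. In heart 42 genes passed with all 24 arrays together. With both arrays of the doubled mouse number left out, 737 genes passed in bone and 0 in white adipose tissue (limma, 2418 at unadjusted p under 0.05), and bone Plcb3 turned to -0.020.

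Whether replicate numbers pair the samples is not given in the sources used here. Same-number correlations of deviations ran from -0.0893 to 0.0611 in bone, -0.181 to 0.265 in heart and -0.0548 to 0.404 in white adipose tissue, where 3 of 4 lay over 0.1 and pairs of other numbers reached 0.332, so pairing stays open there. With a replicate block the counts were 2 in bone, 1306 in white adipose tissue and 0 in heart (limma, 283 at unadjusted p under 0.05).

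Of 126 list tests 18 passed. With no filter 31 passed, and with a correlation estimated per list or with fry's directional test 0 did, where the smallest adjusted p was 0.81 and 0.267. With an estimated correlation the adjustment gave all 18 lists the same adjusted p of 0.81, so that value does not rank them. Before adjustment, camera with an estimated correlation gave them p from 0.00702 (heart immediate early genes) to 0.289 (bone interferon genes). Fry's mixed test, which counts changes in either direction, passed 15 lists, 13 of them in white adipose tissue (endothelin signalling among them, adjusted p = 0.0384) and 3 of them among the 18. In white adipose tissue 29.6% of all genes had an unadjusted p under 0.05 in limma, so such a call is not particular to a list. Other settings gave 14 (brightness) to 22 (median scaling), and leaving out single arrays gave 16 to 23. The 18 lists kept their call in 238 of 306 alternatives, lost it in 65 and reversed in 3. Reversed means that the direction given by camera turned. The reversed ones were ribosome genes in heart under median scaling (-0.083), and MHC class II (0.28) and cell division (0.089) in white adipose tissue with brightness as a covariate. In the heart glucocorticoid and fasting response list the median turned as well, to -0.032 without heterozygous array 4 and to -0.0077 under median scaling, while camera's direction stayed.

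For the genotype difference between bone and white adipose tissue, 544 genes passed with no filter and 113 with all 24 arrays in 1 fit. The latter fit gave 1 gene for heart against bone and 494 for heart against white adipose tissue. Named genes kept the call of their difference in 124 of 140 alternatives and lists in 269 of 322, with 0 reversed.

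Among named genes 2884 of 3273 alternatives kept side and direction, 85 lost a call, 264 gained one and 40 turned in direction. Under cyclic loess heart Plcb3 turned to 0.022 and white adipose Ednrb to -0.0022. Under median scaling heart Ednrb turned to -0.047, heart Rplp1 to -0.056, and Plcb4 to 0.044 in bone and 0.038 in white adipose tissue. With array weights heart Ece1 turned to -0.069 and bone Plcb4 to 0.040. With brightness as a covariate, in heart Gnaq turned to 0.14, Prkca to -0.35 and Ednrb to -0.087, and in white adipose tissue Gna13 turned to -0.0036, Ece1 to 0.019, Plcb3 to -0.014, Ece2 to 0.43, H2-DMa to 0.098, Ciita to 0.33, H2-DMb1 to 0.13 and Cd74 to 0.25.

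With single arrays left out the counts ran from 0 to 1 in heart, 0 to 803 in bone and 0 to 1156 in white adipose tissue, and for differences from 0 to 1972 (bone against white adipose tissue, by animal), 0 to 8 (heart against bone) and 0 to 522 (heart against white adipose tissue). The cause was not tested. Changes of heart genes ran from -0.083 to 0.73 for Ece1, -0.20 to 0.0047 for Plcb3, -0.42 to 0.071 for Gnaq, -0.14 to 0.16 for Prkca and -0.062 to 0.13 for Ednrb. In bone they ran from -0.020 to 0.13 for Gna11, -0.051 to 0.069 for Plcb3 and -0.076 to 0.14 for Plcb4, and in white adipose tissue from -0.090 to 0.015 for Plcb4 and -0.017 to 0.052 for Ednrb.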

Other observations

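The genes in this part, and the arrays left out to show them, were chosen only after their values were seen.

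The 5 eosinophil granule genes below were picked from the largest changes in bone without wild-type array 3, and no list of such genes was fixed or tested. With all arrays the log2 changes were 3.35 for Ear6 (adjusted p = 0.106), 2.42 for Prg3 (0.0917), 2.35 for Prg2 (0.137), 1.89 for Epx (0.11) and 1.46 for Ear10 (0.0568), none past the threshold. Without wild-type array 3 they were 4.18 (adjusted p = 0.0176), 2.99 (0.0127), 2.96 (0.0321), 2.35 (0.0208) and 1.69 (0.00273). The heat shock gene Hspa1a changed by -1.08 with all arrays (adjusted p = 0.212) and by -1.53 without that array (0.023).

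In white adipose tissue without wild-type array 4, the lower genes included Tph2 at -3.54 (adjusted p = 0.0294), Rgs1 at -2.93 (0.0327), the macrophage elastase gene Mmp12 at -2.85 (0.0327), Gpnmb at -2.60 (0.0309), Saa3 at -2.47 (0.0294) and Ccl7 at -2.40 (0.0294). Higher genes included Cyp2e1 and Inmt, each at 1.89 (0.0327). With all arrays none of these passed, with adjusted p from 0.0705 for Tph2 to 0.116 for Gpnmb.

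The circadian clock list in white adipose tissue had a median change of 0.40 and 8 members past the threshold when adjusted over the list alone (7 higher, 1 lower), with adjusted p = 0.14 in camera. Dbp changed by 1.37 (adjusted p = 0.0672), by 1.63 without wild-type array 3 (0.0268), and passed without wild-type array 4 as well (0.0342). The time of day of sampling is not given in the sources used here, and no explanation was tested.

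White adipose heterozygous array 2 carried transcripts of bone, marrow and muscle. The levels below come from normalization within white adipose tissue. Ngp lay at 9.87 against 4.64 to 5.33 on the other arrays of that tissue, Camp at 10.4 against 4.61 to 6.15, S100a9 at 11.9 against 4.66 to 7.21, Bglap2 at 8.69 against 4.60 to 4.75 and Ckm at 8.25 against 4.50 to 4.91. The muscle gene Acta1 differed less, at 12.1 against 10.7 to 11.5, and was detected on all 7 other arrays. Muscle transcripts were thus not confined to this array. S100a9 was also detected on 3 other arrays and Camp on 2. Without this array 0 genes passed in white adipose tissue in limma and Depp1 had adjusted p = 0.115.

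Deviations from the group mean did not run together in bone and white adipose tissue of an animal, with correlations between -0.266 and 0.0397. The lowest belongs to wild-type animal 3, whose bone array lies near the heterozygous ones.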
